A study of Pyropia tenera with 4 samples.

How the data were processed

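RNA from blades of the red alga *Pyropia tenera*, the seaweed grown as laver, was measured on 4 one-colour (Cy3) Agilent arrays, 1 array per group. The groups were a non-infected control blade, a blade infected with *Olpidiopsis pyropiae* (an oomycete that causes Olpidiopsis blight), a blade infected with PyroV1 (a virus, green spot disease) and a blade infected with *Pythium porphyrae* (an oomycete that causes red rot). Per the labels' protocols, both oomycete-infected blades were collected 72 h after inoculation, and the sampling time of the PyroV1 blade was not given in the sources used here. Groups were taken from the labels. All 4 arrays lay on 1 slide, in the order control, *O. pyropiae*, PyroV1, *P. porphyrae*, so position on the slide and group cannot be told apart. The labels name no more than 1 sample in each group, so no test across samples was possible and no p-value is given. The series' design text speaks of a comparison made 3 times without saying whether blades, extracts or hybridisations were repeated, so it is not known whether a sample pools several blades; each file holds 1 array.

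Per the file headers, the authors' intensity values came from Agilent Feature Extraction 11.5.1.1, which subtracted background and removed a spatial trend within each array. The deposited processed intensity was not scaled between arrays, and the dimmest spots of an array share 1 low surrogate value, 3.54 on the control array and 5.63 on the *P. porphyrae* array. The deposited background-level and spot-level median intensities, per the file headers, are pixel brightness before that correction. Other deposited columns, per the file headers, hold flags and grid positions. A further deposited table holds 1 linear intensity per probe. It equals the mean of both spots within a tolerance of 1 part in 10000 for 92.6% of probes on the control array and for 94.1% on the PyroV1 array, with the other arrays between these. Its column medians were 37.0, 45.6, 29.9 and 47.3 for control, *O. pyropiae*, PyroV1 and *P. porphyrae*. Its scale is linear, it was not centred, and it has no direction since each column is 1 array.

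Each array held 15114 probes designed from expressed sequence tags of *P. tenera*, each spotted 2 times. The files give contig identifiers and pair none of them with a gene name, so the gene lists fixed beforehand were not tested and contigs are named by identifier. Identifiers come in 2 series, TT0395 with 6255 probes and TT0424 with 8859 probes, whose meaning the files do not state. The rule fixed for this case names at most 2 contigs higher and 2 lower per comparison, by size of the ratio, among probes well above background on at least 1 of the 2 arrays, saturated on neither, and with spots that do not overlap between the arrays. It was applied to each infection against the control, to all 3 infections against the control (by the smallest of the 3 ratios), and to each infection against the nearest of the other 3 arrays.

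The processed intensity was converted to log2, the array's 75th percentile over the 15114 probes was subtracted, and both spots were averaged. A probe was called detected where both spots were well above background; asking for both spots was settled after the files had been seen. A probe was counted where it was detected on at least 1 of the 2 arrays compared and its ratio was at least 2-fold. Where a named contig was not detected on 1 side, that side was set at the higher of its own level and the lowest level detected on that array, and the fold is given as "at least". That bound belongs to this setting: a higher floor or normexp, whose offset compresses dim signals, gives smaller folds, which are printed where they differ by over 1.5 times. Scaled signals are in intensity units at the geometric mean of the 4 arrays' 75th percentiles. The only error available for each probe is the spread between duplicate spots, which is technical and leaves out differences between blades, RNA extracts, labellings and arrays. The number of arrays limits the precision.

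Counts and correlations were tested on simulated arrays made from the 8553 probes detected on the control array with the measured spot error. The mean difference between spot 1 and spot 2 of each array was first taken off that error. Of 200 probes changed 3-fold, 98% were counted for *O. pyropiae*, 99% for PyroV1 and 96.5% for *P. porphyrae*. Of 200 changed 4-fold, 100% were counted in each comparison. Of 200 changed 1.5-fold, 4.5%, 7% and 6.5% were counted in the same order. The simulation without any change gives the values set beside the shared counts and correlations below. Every simulated probe was treated as detected on all arrays. Neither these shares nor the counts from spot error alone therefore apply to probes dim on an array compared. Intervals for correlations and covariances are 95% bootstrap intervals over probes (1000 draws), which treat probes as independent.

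The alternatives fixed before the data were examined were median centring, quantile normalization, normexp background correction, no detection filter, detection on both arrays, a 3-fold threshold, non-overlapping spots, the authors' value table and a floor at the 5th percentile of detected signals. Normexp (offset 50) was run on median spot signals, since the files hold no mean spot signals. Added after seeing the data were detection on either spot, the percentile over probes detected on all 4 arrays, removal of a smooth surface in row and column (polynomial of degree 4), each spot alone, and non-uniform spots left out. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp and quantile normalization.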

Results

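Transcript levels of *Pyropia tenera* blades carrying 3 different diseases were compared with those of a non-infected blade, with 1 array per group. Signal strength differed between the arrays. The 75th percentile of the processed signal was 327 intensity units for the control, 358 for *Olpidiopsis pyropiae*, 222 for PyroV1 and 401 for *Pythium porphyrae*. Of 15114 probes, 8553 (56.6%) were detected on the control array, 8456 (55.9%) on the *O. pyropiae* array, 7317 (48.4%) on the PyroV1 array and 7913 (52.4%) on the *P. porphyrae* array. No spot of these probes was saturated. The 100 brightest probes held 49.0% of the summed signal on the PyroV1 array and 37.3% to 40.7% on the other arrays.

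Duplicate spots of a detected probe had an SD of 0.31 (log2) on the control array, against 0.24 for *O. pyropiae*, 0.23 for PyroV1 and 0.24 for *P. porphyrae*. These SDs leave out the mean difference between spot 1 and spot 2. It was 0.17 (log2) on the control array, against 0.001 for *O. pyropiae*, 0.004 for PyroV1 and 0.006 for *P. porphyrae*. Spots of 1 probe lay at least 2-fold apart for 3.76% of detected probes on the control array and for 1.18% to 1.63% on the infected arrays. This spread is the only error that can be estimated probe by probe. It leaves out differences between arrays, and some array control probes, described further below, differed by more than 2-fold between arrays after scaling. No ratio below has a replicate check.

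**Figure D1:**
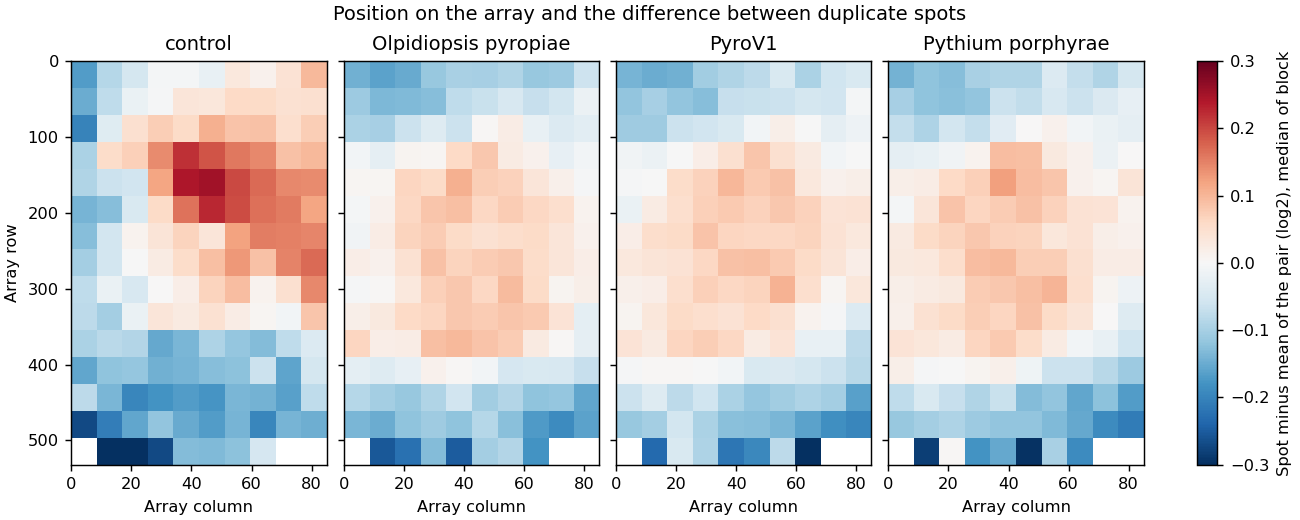
Difference of each spot from the mean of its duplicate pair (log2, colour), as the median over blocks of array rows (vertical axis) and array columns (horizontal axis), for the 4 arrays. Blocks of the control array span a wider range of colours than those of the 3 infected arrays, whose spot SDs were 0.23 to 0.24 against 0.31.

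The first comparison asked which transcripts differed in the blade with Olpidiopsis blight, 72 h after inoculation. Contig EPT001TT0424C008059 was 3689-fold higher than in the control, with scaled signals of 382747 and 104 and spot SDs of 0.01 and 0.09 (log2). Contig EPT001TT0424C005259 was at least 1391-fold higher, with a scaled signal of 24346 against a control spot pair not well above background. In the other direction, EPT001TT0424C002367 was 176-fold lower (34.5 against 6053, spot SDs 0.22 and 0.44), and EPT001TT0424C007176 was at least 151-fold lower, its signal in the control being 3129.6. Of 9091 probes tested, 1500 were at least 2-fold higher and 1167 at least 2-fold lower, together 29.3%. With a floor under the signals, which bounds the dim side less tightly, the first 2 folds were 3689 and 603 and the last 2 were 150 and 77.5. With normexp they were 2222, 354, 65.4 and 38.2. Not all of these contigs were particular to this blade. With PyroV1, EPT001TT0424C008059 was also higher than the control, by 8.44 (log2). EPT001TT0424C002367 and EPT001TT0424C007176 were not well above background on the PyroV1 array, at scaled signals of 6.74 each. With *P. porphyrae*, these contigs differed from the control by 1.16, -0.90 and -0.90 (log2), in the same order. At least 8-fold differences were found for 148 higher and 187 lower probes. Spot error alone gave 12 higher and 13 lower in the simulation on 8553 probes. The direction of the balance depended on scaling: 56.2% of the probes past 2-fold were higher, but 42.96% with the percentile taken over probes detected on all 4 arrays, which moved the median ratio by -0.22 (log2).

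The second comparison concerned green spot disease. Contig EPT001TT0424C004449 was at least 29879-fold higher with PyroV1 than in the control, at a scaled signal of 522794 (spot SD 0.02). Contig EPT001TT0395C005642 was at least 14802-fold higher, at 258990 (spot SD 0.27). Both were not well above background on the control and *O. pyropiae* arrays and were detected on the *P. porphyrae* array at 378 and 72.0. Contig EPT001TT0395C003984 was at least 1940-fold lower, from a control signal of 65800 (spot SD 0.02), and EPT001TT0424C002701 at least 476-fold lower, from a control signal of 16160 with a spot SD of 0.77. With the floor these 4 folds were 12946, 6413, 1629 and 400.2, and with normexp 6920, 3237, 572 and 156, so each bound holds for the main setting only. EPT001TT0395C003984 was also lower than the control with *O. pyropiae* (-4.88 log2) and *P. porphyrae* (-2.30). So was EPT001TT0424C002701 (-1.65 and -4.92). Of 8880 probes tested, 1815 were at least 2-fold higher and 1882 at least 2-fold lower, together 41.6%, with 339 and 389 past 8-fold. Spot error alone gave 8 and 10. Probes detected in the control with neither spot detected under infection numbered 1142, against 191 the other way. Fewer probes were detected on the PyroV1 array than on any other. Requiring detection on both arrays left 1494 higher and 1078 lower probes, so that the higher probes outnumbered the lower. Without a detection filter the counts were 3109 and 2078, but these take in undetected spots. After scaling, the surrogate value of dim spots lay 0.96 (log2) higher on the PyroV1 array than on the control array, just under 2-fold. The unfiltered counts therefore lean towards higher with PyroV1, by an amount not tested.

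The third comparison concerned red rot, 72 h after inoculation. Contig EPT001TT0395C003161 was 479-fold higher with *P. porphyrae*, at a scaled signal of 10459 against 21.8 (spot SDs 0.35 and 0.03). Contig EPT001TT0395C003254 was 206-fold higher, at 28429 against 138. Contig EPT001TT0395C003477 was 37.5-fold lower, at 1786 against 66879 (spot SDs 0.09 and 0.60). EPT001TT0424C002701, also among the lowest with PyroV1, was 30.2-fold lower. None of these contigs differed from the control with *P. porphyrae* alone. EPT001TT0395C003161 is taken up below. EPT001TT0395C003254 was higher by 8.01 (log2) with PyroV1 and by 3.28 with *O. pyropiae*. EPT001TT0395C003477 differed by -3.08 and -2.37 in the same order, and EPT001TT0424C002701 by -1.65 with *O. pyropiae*. All these ratios share the control array. The 479-fold ratio of EPT001TT0395C003161 was 259-fold with a floor under the signals and 115-fold with normexp. Of 8811 probes tested, 932 were at least 2-fold higher and 1119 at least 2-fold lower, together 23.3%, with 82 and 84 past 8-fold. Spot error alone gave 9 and 14. Requiring detection on both arrays left 759 higher and 745 lower probes, which turned the balance, and a floor left 719 and 724, close to equal numbers.

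**Figure D2:**
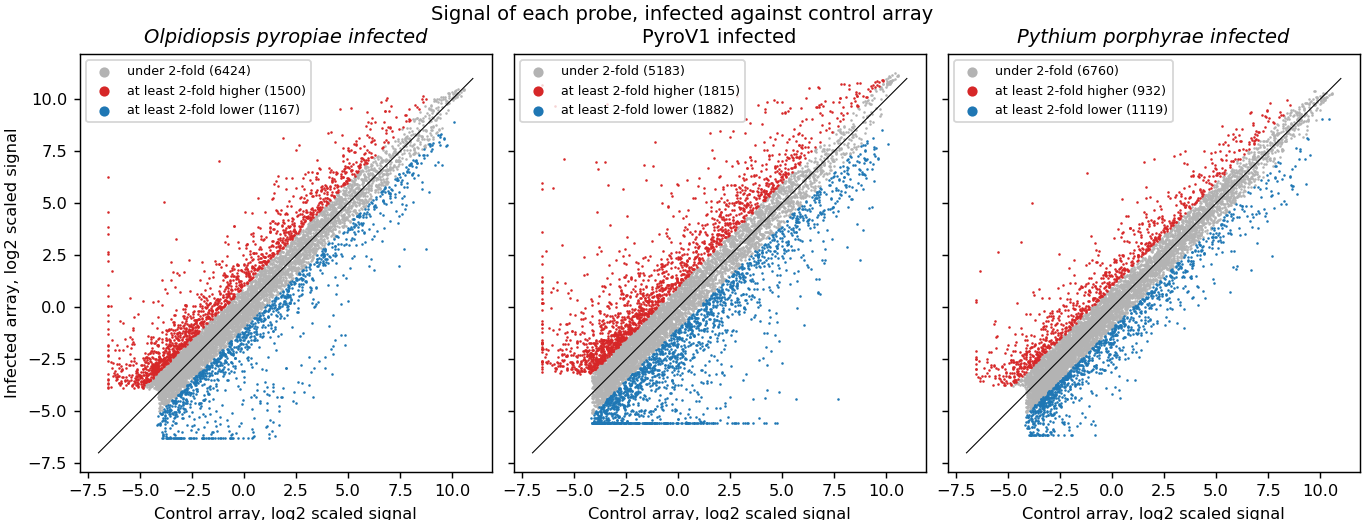
Scaled signal (log2) on the infected array (vertical axis) against the control array (horizontal axis) of each probe detected on at least 1 of them, 1 panel per infection. The line marks equal signal. Red points are at least 2-fold higher, blue points at least 2-fold lower and grey points under 2-fold. The PyroV1 panel holds 1815 red and 1882 blue points, against 1500 and 1167 for *O. pyropiae* and 932 and 1119 for *P. porphyrae*; points in straight rows at the edges sit at the surrogate value of dim spots.

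The ratios were also compared across infections. Contig EPT001TT0395C003161 was higher in all 3 infections, at scaled signals of 10549 (*O. pyropiae*), 31599 (PyroV1) and 10459 (*P. porphyrae*) against 21.8. Contig EPT001TT0395C002630 was at least 2-fold higher in all 3 as well, with a smallest ratio of 23.3-fold. Contig EPT001TT0395C003881 was lower in all 3, with a smallest ratio of 12.1-fold, and EPT001TT0424C001258 was the other contig that the rule names. Its duplicate spots on the *P. porphyrae* array had an SD of 2.46 (log2), and its ratio there was -4.64 (log2) in the main setting, -2.89 with the authors' value table and -3.18 from spot 2 alone, so no fold is given for it. In total 264 probes were at least 2-fold higher in all 3 infections and 342 at least 2-fold lower. Independent lists of the probes past 2-fold, among the 8623 tested in all 3 comparisons, would share 20.2 and 33.1, and spot error on unchanged arrays gave 0 and 1. All 3 ratios share 1 control array, which cannot be split, so part or all of the excess may come from that array. The 342 lower probes are the same probes that stood at least 2-fold above all other arrays in the control. Single infected arrays stood so far above the others for 295 to 737 probes and below them for 110 to 748. Requiring detection on both arrays of each comparison left 231 higher and 187 lower, which turned the balance.

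Pairs of infections shared 730 higher and 876 lower probes for *O. pyropiae* and PyroV1, where independent lists among the probes tested in both comparisons would share 240.5 and 252. *O. pyropiae* and *P. porphyrae* shared 449 and 437 (120.05 and 150.2 for independent lists), and PyroV1 and *P. porphyrae* shared 377 and 595 (148 and 244). Spot error on unchanged arrays sharing the control gave 0 to 3 shared probes per pair and direction. Across the 6749 probes detected on all 4 arrays, which are not independent replicates, the log2 ratios of *O. pyropiae* and PyroV1 had a Pearson correlation of 0.60 (interval 0.57 to 0.63). It was 0.49 (0.45 to 0.51) for *O. pyropiae* and *P. porphyrae*, and 0.42 (0.39 to 0.44) for PyroV1 and *P. porphyrae*. Unchanged arrays sharing 1 control gave 0.62, 0.63 and 0.63 in the simulation on 8553 probes, above all 3 measured correlations. Without any change the simulated correlation is set by the spot errors of the arrays alone. It is therefore no level against which the measured correlations can be judged. The covariances were 0.92, 0.47 and 0.56, against simulated covariances of 0.05 each. The simulated covariances hold spot error alone. Any blade, extract, labelling or array error of the single control adds to all 3 measured covariances, so their excess cannot be read as a shared response.

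Infected arrays were set against each other without the control. With *O. pyropiae*, 1522 probes were at least 2-fold higher than with PyroV1 and 1131 at least 2-fold lower. That balance turned with detection on both arrays (857 higher and 930 lower) and without a detection filter (1851 and 1987). The unfiltered counts take in undetected spots, whose surrogate value after scaling was 4.09 for *O. pyropiae* and 6.74 for PyroV1. Against *P. porphyrae*, *O. pyropiae* had 1560 higher and 979 lower probes, and PyroV1 had 1717 higher and 1659 lower. Median centring turned both balances, to 1211 and 1292 for *O. pyropiae* and to 1445 and 1877 for PyroV1. For PyroV1 so did quantile normalization (1569 and 1730) and the percentile over detected probes (1623 and 1729), which did not turn the *O. pyropiae* balance. Spot error alone gave 6 to 17 probes per direction. Over the 6749 probes, the SD of the log2 ratio was 0.92 between control and *P. porphyrae*, 1.01 between *O. pyropiae* and *P. porphyrae*, and 1.05 between control and *O. pyropiae*. It was 1.18 between *O. pyropiae* and PyroV1, 1.37 between PyroV1 and *P. porphyrae*, and 1.46 between control and PyroV1.

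Some probes stood apart on a single array. Of 9350 probes detected on any array, 737 were at least 2-fold above and 748 at least 2-fold below all other arrays with PyroV1. The counts were 387 and 110 for *O. pyropiae*, 295 and 326 for *P. porphyrae*, and 342 and 310 for the control. The 342 are the probes counted above as lower in all 3 infections. With PyroV1, EPT001TT0395C005642 was 3598-fold and EPT001TT0395C006086 2837-fold above the nearest other array, while EPT001TT0424C008261 was 120-fold and EPT001TT0395C004752 at least 84.4-fold below it. With *O. pyropiae*, EPT001TT0424C005259 was at least 718-fold and EPT001TT0424C003874 303-fold above, and EPT001TT0424C007022 and EPT001TT0395C005426 were 44.3-fold and 43.9-fold below. With *P. porphyrae*, EPT001TT0424C008651 and EPT001TT0424C005343 were 11.5-fold and 11.1-fold above, and EPT001TT0424C003541 and EPT001TT0395C002110 were 17.3-fold and 14.6-fold below. With normexp, the folds above the nearest array were 1735 and 1580 with PyroV1, 277 and 193 with *O. pyropiae*, and 5.48 and 4.45 with *P. porphyrae*. EPT001TT0395C004752 was then 34.1-fold and EPT001TT0424C007022 21.5-fold below.

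Probes were also sorted by the arrays on which they were on (both spots detected) and off (neither spot detected). With at least a 4-fold gap between the dimmest on array and the brightest off array, 37 probes were on with PyroV1 alone, 17 with *O. pyropiae* alone, 1 in the control alone and 0 with *P. porphyrae* alone. PyroV1 was the only array off for 39 probes. A further 47 probes were on in the control and with *P. porphyrae* and off with *O. pyropiae* and PyroV1. The other 5 ways of having 2 arrays on and 2 off held 0, 0, 1, 1 and 2 probes. The 4-fold gap was picked after gaps of 4-, 8- and 16-fold and no gap at all had been looked at: control with *P. porphyrae* held 27 probes at 8-fold and 12 at 16-fold, and with no gap it held 132, fewer than the 143 of control with *O. pyropiae*. Of the 47 probes, 41 (87.2%) were TT0424 contigs, against 55.3% of the probes detected on both on arrays. This excess was not particular to the set. Of the 39 probes off with PyroV1 alone, 30 (76.9%) were TT0424 contigs, against 54.9% of the probes detected on their on arrays. For the 37 probes on with PyroV1 alone the share was 59.5%, against 54.4%.

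**Figure D3:**
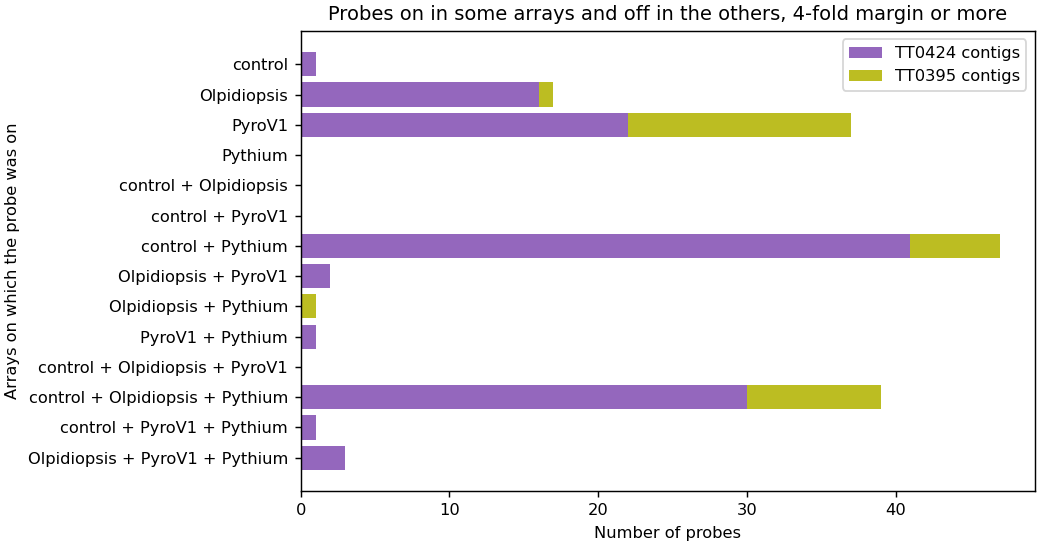
Number of probes (horizontal axis) that were on in the arrays named on the vertical axis and off in the others, with a gap of at least 4-fold; colours show the contig series TT0424 and TT0395. The longest bars are control + Pythium (47), control + Olpidiopsis + Pythium (39) and PyroV1 (37).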

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

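All tests weighed in this part were chosen after the result they bear on had been seen, and the rule that gives control-probe folds as bounds was revised after first values had been seen. Some probes were at least 2-fold higher than the control under an infection and at least 2-fold lower under another; with 1 array per group these differences were not tested. With *O. pyropiae* higher, 145 probes were lower with PyroV1 and 62 lower with *P. porphyrae*. With PyroV1 higher, 24 were lower with *O. pyropiae* and 85 lower with *P. porphyrae*. With *P. porphyrae* higher, 80 were lower with *O. pyropiae* and 133 lower with PyroV1.

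Array control probes, which no comparison above uses, were at least 2-fold brighter on some infected arrays than on the control array after scaling. On the *O. pyropiae* array, DCP_20_7 was at least 16.7-fold, DCP_20_9 at least 15.3-fold, DCP_20_1 at least 2.41-fold, DCP_20_0 2.30-fold, DCP_22_4 2.05-fold and the probe (+)E1A_r60_a20 at least 2.01-fold brighter. On the PyroV1 array, GE_BrightCorner was 4.36-fold, DCP_22_4 2.47-fold, DCP_22_7 2.36-fold, DCP_22_2 2.18-fold, DCP_22_6 2.04-fold and (+)eQC-40 2.02-fold brighter. On the *P. porphyrae* array, GE_BrightCorner was 2.24-fold brighter. It was brighter on the *O. pyropiae* array too, by 0.94 (log2). Differences of this kind between arrays are not part of the spot error, so the counts from spot error alone leave them out. Their cause was not tested. Others were dimmer: ETG05_66023 differed from the control by -1.89 (log2) on the *O. pyropiae* array and by -2.19 on the *P. porphyrae* array, and was not well above background on the PyroV1 array. On the *P. porphyrae* array, (+)E1A_r60_a22 differed by -1.50, and DCP_22_0, DCP_22_2, DCP_22_4, DCP_22_6 and DCP_22_7 differed by -1.65 to -1.32, with all spots well above background on both arrays.

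A pattern weighed further is the set of 47 probes that were on in the control and *P. porphyrae* arrays and off in the others, at the 4-fold gap picked after seeing the counts. Spot noise at the detection limit is argued against by duplicate spots: of 60 probes chosen for the pattern on spot 1 alone, 88.3% (Wilson 95% interval 77.8% to 94.2%) showed the 4-fold gap on spot 2, a test that leaves out errors shared by both spots of an array. A flaw in a region of an array was first tested by the distance between their spots, whose median lay at percentile 11.54 of 10000 random sets, between the bounds set for either verdict. A test added afterwards argues against a flaw that takes in neighbouring spots. Of 445 neighbouring spots that were on in the control and *P. porphyrae* arrays, 1.12% were off in the others, against 3.06% of all such spots. The written rule for dismissing a flaw also asked for a wider distance than was found, so by that rule the question stays open. RNA of another organism of fixed composition in these 2 samples stays open, since the SD of the *P. porphyrae* to control ratios of the set lay at percentile 28.8 of level-matched random sets, and so does a difference caused by infection, which was not tested beyond the arrays themselves. A difference between single blades or RNA extracts stays open too, since 1 array per group cannot tell it apart from infection.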

How the results depend on the processing

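Alternatives on detection by either spot, the percentile over detected probes, the position surface, single spots, non-uniform spots and normexp on median signals were chosen after seeing the data. No correlation or named ratio changed sign under any setting run, but the balance of higher and lower probes did: 56.2% of the *O. pyropiae* probes past 2-fold were higher, against 47.4% with median centring and 42.96% with the percentile over detected probes, and the *P. porphyrae* share went from 45.4% to 51.4% with median centring and to 39.6% with the percentile over detected probes. The PyroV1 share was 49.1%, against 59.9% without a detection filter, 58.1% with detection on both arrays, 45.3% with median centring and 43.2% with the percentile over detected probes. The unfiltered share takes in undetected spots, whose scaled surrogate value was 0.96 (log2) higher on the PyroV1 array than on the control array. Of the counts under alternatives, 172 stayed within 1.5 times their main value and 38 did not. Of the correlations, 34 stayed inside their intervals and 2 did not. Of the named ratios, 295 moved by less than the spot error and 68 by more. That spot error is not the contig's own spread. With *O. pyropiae*, EPT001TT0424C008059 went from 11.85 to 12.09 (log2) with the position surface removed and is among the 295, though its spot SDs were 0.01 and 0.09. The counts stayed within 1.5 times under median centring, quantile normalization, the authors' value table, non-overlapping spots and every added setting except normexp. The cause of the moves was not tested except where the setting itself changes what is counted.

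At a 3-fold threshold, which counts fewer probes by construction, the higher and lower counts against the control were 730 and 578 (*O. pyropiae*), 1038 and 1189 (PyroV1), and 427 and 502 (*P. porphyrae*); all 3 infections shared 83 and 125. Between infections they were 940 and 562 (*O. pyropiae* over PyroV1), 764 and 527 (*O. pyropiae* over *P. porphyrae*), and 955 and 1075 (PyroV1 over *P. porphyrae*). With normexp, they were 859 and 711, 1095 and 1104, and 569 and 534 against the control, 165 and 176 in all 3, and 866 and 664, 808 higher (*O. pyropiae* over *P. porphyrae*), and 1095 and 1073 between infections; the PyroV1 and *P. porphyrae* correlation was 0.381. Without a detection filter, which adds dim probes, 3109 (PyroV1) and 1562 (*P. porphyrae*) were higher, and 400 in all 3. Between infections, 1987 were lower and 1851 higher with *O. pyropiae* than PyroV1, and 2922 were higher with PyroV1 than *P. porphyrae*. The *O. pyropiae* and *P. porphyrae* correlation was then 0.409. With detection on both arrays, which drops dim probes, 1078 (PyroV1) and 745 (*P. porphyrae*) were lower. In all 3 infections, 187 were lower and 231 higher. With *O. pyropiae*, 857 were higher and 930 lower than with PyroV1, and 1007 were lower with PyroV1 than *P. porphyrae*. With a floor, 724 were lower with *P. porphyrae*.

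The median of 2 spots equals their mean, so that alternative changes nothing. The gene-list alternatives were not run, and detection on both arrays and non-overlapping spots were not run for the correlations and named ratios. Median centring moved the median ratio of *O. pyropiae* by -0.15 (log2); the percentile over detected probes moved it by -0.22 and that of PyroV1 by -0.13. Probes dim on either array have bounds only, and the PyroV1 array had the fewest detected probes. No paired analysis was possible because each group has 1 array.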

Other observations

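The tests on shared control error and on slide position were chosen after their results had been seen, as was the bootstrap interval on the spot SD ratio; the tests on large ratios and on the surface were written before. Both contig series held differing probes. Of TT0395 probes tested, 21.6% were at least 2-fold higher and 19.2% lower with PyroV1, against 19.5% and 22.8% of TT0424 probes. With *O. pyropiae*, 16.0% were higher and 12.0% lower in TT0395, against 16.9% and 13.5% in TT0424. With *P. porphyrae*, 11.01% and 13.2% stood against 10.2% and 12.3%. Of the 17 probes on with *O. pyropiae* alone at the 4-fold gap, 16 were TT0424 contigs, against 22 of the 37 on with PyroV1 alone. TT0424 contigs made up 54.8% of the probes detected on the *O. pyropiae* array and 54.4% of those detected on the PyroV1 array.

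Of the 3 pairs of infections, *O. pyropiae* and PyroV1 had the highest correlation and covariance of ratios. Their shared lower probes were 3.48 times the independent expectation, against 2.91 for *O. pyropiae* with *P. porphyrae* and 2.44 for PyroV1 with *P. porphyrae*, but their shared higher probes were 3.04 times it, against 3.74 and 2.54, and that expectation leaves out the shared control. Error of the control array shared by the ratios adds the same amount to the covariance of every pair, so it may raise all 3 but is argued against as the cause of their order: the ratio of *O. pyropiae* to control and that of PyroV1 to *P. porphyrae*, which share no array, had a covariance of 0.448 (interval 0.389 to 0.522), the difference of the covariances of *O. pyropiae* with PyroV1 and with *P. porphyrae*. The other pairings without a shared array gave -0.359 (PyroV1 to control with *P. porphyrae* to *O. pyropiae*) and -0.0897 (*P. porphyrae* to control with *O. pyropiae* to PyroV1), and the 3 sum to 0 by construction. A few extreme probes are argued against by a Spearman correlation of 0.280 for the first pairing. Slide position stays open: the arrays at the ends of the slide, control and *P. porphyrae*, had the smallest SD of the 6 pairs (0.920), which a difference between middle and end positions would also give. Other pairs go against position as the only source of the differences. Each SD also holds differences of infection and blade, so a position effect beside those is not excluded. Neighbouring pairs had SDs of 1.05, 1.18 and 1.37, not the smallest as nearness would give. The middle arrays, *O. pyropiae* and PyroV1, differed by 1.18, more than *O. pyropiae* from the control (1.05) or *P. porphyrae* (1.01). A difference between single blades or RNA extracts stays open as well, since 1 array per group cannot tell it apart from the infections.

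Duplicate spots differed more on the control array than on the others. Removing a smooth surface in row and column lowered the spot SD on every array (control 0.31 to 0.23 log2; *O. pyropiae* 0.24 to 0.18; PyroV1 0.23 to 0.17; *P. porphyrae* 0.24 to 0.19). The control SD was 1.29 times the highest of the others before and 1.24 times afterwards (interval 1.17 to 1.32). A smooth gradient as the whole cause was predicted to leave at most 1.1, so the surface removed is argued against as the whole cause; the interval was added after the value was seen, and it still holds 1.2, the bound written beforehand for ruling a gradient out. A gradient of another shape and a lower quality of the control spots were not tested. The surface did not set the counts: the summed count of probes past 2-fold changed by a factor of 1.02 when the surface was removed.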
